A study of Mus musculus with 6 samples.

How the data were processed

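Messenger RNA was sequenced from 6 subcutaneous tumours of LLC1 cells, the Lewis lung carcinoma line of C57BL/6 mouse origin, grown in mice that carry a beta-hCG transgene. The hosts were offspring of C57BL/6 females and transgenic FVB males. The labels define 3 groups of 2 libraries: tumours of transgenic mice with no ovariectomy or supplementation named, of ovariectomized transgenic mice given vehicle, and of ovariectomized transgenic mice given progesterone. Supplementation lasted 28 days and tumours were taken 30 days after implantation. Per the labels' protocols, tissue was homogenized in liquid nitrogen, RNA was extracted with TRIzol and treated with DNase, and 500 ng of total RNA entered a directional mRNA library kit with 11 cycles of indexing PCR. The libraries hold RNA of the tumour cells and of all host cells in the tumour, both mouse, and the gene counts used here do not separate the 2 sources.

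The deposited table gives raw read counts per gene for all 6 libraries, with no normalization. The submitters' processing notes name HISAT2, HTSeq and DESeq and the genome build GRCm38.p6; versions and settings, including whether counting used the strand, are not given in the sources used here. The table holds 19288 Ensembl gene IDs, of which 19284 were found in the GENCODE annotation of GRCm38, the source of all coordinates (1-based). No count column was left unused. Where 1 symbol had more than 1 gene ID, gene lists used the ID with the larger total count. Genes with near-identical or related copies, such as Hspa1a and Hspa1b, H2-Q6 and H2-Q7, Hba-a1 and Hba-a2, Tpsb2 and Tpsab1, Prl2c2 and Prl2c3, or Rpl17 and Rpl29 with their pseudogenes, can share reads to differing degrees, and their separate values are uncertain.

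Library totals ran from 19526775 to 30083925 counts, so 3 counts, taken as the limit that a count of 0 allows, correspond to 0.154 CPM in the shallowest library and 0.0997 CPM in the deepest. These limits cover counting error only, since PCR duplicates were not marked by molecular identifiers. Counts were analysed in R 4.3.3. Genes were kept with edgeR 4.0.16 (filterByExpr, 13632 genes), library sizes were scaled by TMM, and 1 quasi-likelihood model (glmQLFit and glmQLFTest) was fitted to all 6 libraries with 1 mean per group and 3 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Log2 fold changes are edgeR's, standard errors were derived from its F statistic, and CPM values are TMM-scaled and given as mean ± SD of 2 libraries. The labels number the libraries 1 and 2 but do not say that each came from a separate animal, so p-values measure the spread between these libraries.

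In all, 40 gene lists were fixed before the data were examined, and 38 had at least 3 members past the filter. Lists of pathways covered hormone receptors, progesterone and glucocorticoid receptor targets, oestrogen receptor targets, steroid synthesis and metabolism, cell cycle, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, unfolded protein response, cholesterol synthesis, matrix remodelling enzymes, epithelial to mesenchymal transition, angiogenesis, interferon response, MHC class I and class II presentation, Toll-like receptor pathway, inflammatory cytokines and chemokines, immune suppression and checkpoints, drug efflux and resistance, immediate early and heat shock genes, and mitochondrially encoded genes. Marker lists covered T cells, cytotoxic and NK cells, B and plasma cells, macrophages and monocytes, neutrophils, dendritic cells, mast cells and basophils, endothelial cells, fibroblasts, pericytes and smooth muscle, adipocytes, skeletal muscle, mammary epithelium, red blood cells, nerve and Schwann cells, and the lung epithelial lineage of LLC cells. Sex chromosome genes had 0 members in the table and skin keratinocytes had 2 past the filter, so these lists were not tested. Lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, which compares a list with the other genes, and adjusted over the 38 lists. The same test with a correlation estimated for each list, and fry, were run beside it. List means per library are means of log2 CPM with a prior count of 2.

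Named genes followed a rule fixed before the data were examined. Up to 10 called genes per direction were to be named, with at least 5 CPM in the higher group, no overlap of the 2 groups and an informative symbol, and empty places were filled by smallest unadjusted p under the same conditions. For each list, up to 4 called members were to be named, or, in a called list without any, up to 4 members by smallest p, as values. Hormone receptors that passed the filter are given. Some genes that the rule names are not reported here, and no others took their places. For genes called in opposite directions in the 2 comparisons that use the vehicle tumours, 8 were to be named. No gene was called, so all gene values are of genes that did not pass the test.

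The alternatives were other scalings (median-of-ratios factors, library totals), other filters on low counts (none, at least 1 CPM in 2 libraries, a mean of at least 5 CPM), DESeq2 1.42.0, limma-voom, fits to the 4 libraries of 2 groups, a replicate block, a log2 fold change of at least 1, and leaving out each library in turn. The edgeR fits with its newer dispersion method and with robust estimation were chosen after seeing the data. The programs were tested on simulated counts drawn from the real gene means, library sizes and dispersions, with some of the 13632 genes changed. In the vehicle against transgenic simulation, edgeR recovered 11.3% of 62 genes changed by 1 log2 unit, 62.9% of 70 changed by 2 and 85.3% of 68 changed by 3, with 6 false calls. DESeq2 recovered 30.6%, 77.1% and 89.7% of the same genes, with 44 false calls. These rates hold for independently drawn genes and the numbers of genes changed in the simulation. They do not give the share of changed genes found in the real data, where Scara5, higher by 17.8-fold, had an adjusted p of 0.587 by edgeR. With 2 of the lists moved by a fixed amount in independent genes, both were called, and 1 other list was. The figures were drawn with matplotlib 3.10.9.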

Results

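The series profiled the transcriptomes of LLC1 tumours from beta-hCG transgenic mice, to describe the molecular makeup of tumours in these hosts. Beta-hCG is the hormone-specific subunit of human chorionic gonadotropin, which acts on the luteinizing hormone receptor of the gonads, and ovariectomy removes the ovary as a source of progesterone and oestrogen. The 3 groups of 2 libraries were tumours of transgenic mice (transgenic tumours), of ovariectomized transgenic mice given vehicle (vehicle tumours), and of ovariectomized transgenic mice given progesterone (progesterone tumours). Total counts were 26968095 and 23466357 in the transgenic libraries, 30083925 and 19526775 in the vehicle libraries, and 25892142 and 22954543 in the progesterone libraries. The deepest and the shallowest library were thus both vehicle tumours. CPM values below are given as mean ± SD (n = 2 libraries per group) and log2 fold changes with their standard error.

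Replicates differed far more than sampling noise, with a chi-square per degree of freedom of 94.2 in the transgenic, 38.1 in the vehicle and 62.6 in the progesterone group. The common biological coefficient of variation was 0.295. Across genes, the Spearman correlation was 0.969 between the transgenic libraries, 0.986 between the vehicle libraries and 0.974 between the progesterone libraries. Transgenic library 1 correlated with both vehicle libraries at 0.985 and 0.987, above its 0.969 with transgenic library 2. The first principal component held 31.5% of the variance and placed transgenic library 2 at -54.5, with the other libraries between -23.2 and 32.7. The second held 27.4% and placed progesterone library 2 at 62.9, with the others between -22.3 and 0.68.

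The first comparison set vehicle tumours against transgenic tumours. By the labels these groups differ both by ovariectomy and by 28 days of vehicle, and the effects of the 2 cannot be told apart. Cell cycle genes fell as a list in the vehicle tumours, with a median log2 fold change of -0.81 and 24 of 25 members lower. The list was called at an adjusted p of 1.71e-26 by camera, and at adjusted p = 0.468 with an estimated correlation it was not. Of its members 23 passed adjusted over the list alone, and 0 over all 13632 genes. Among the members, Rrm2 (ENSMUSG00000020649), a subunit of ribonucleotide reductase, had 160 ± 4.51 CPM in transgenic and 77.1 ± 0.801 in vehicle tumours (log2 fold change -1.06 ± 0.14 SE, adjusted p = 0.587 by edgeR). Cyclin A2 (Ccna2) had 161 ± 8.75 against 81.1 ± 14.3 CPM, cyclin B1 (Ccnb1) 98.3 ± 0.286 against 57.5 ± 2.29, and survivin (Birc5) 83.1 ± 8.32 against 45.0 ± 6.25. The replication genes Fen1 and Pclaf had log2 fold changes of -0.78 and -1.09, Cks1b had -0.70, and Dnajc9, a histone chaperone, -0.84.

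Hypoxia and glycolysis genes rose as a list in the vehicle tumours, with a median of 0.51 and 26 of 27 members higher (camera adjusted p = 4.96e-14; adjusted p = 0.468 with an estimated correlation). In this list 8 members passed adjusted over the list alone, and 0 over all genes. The glucose transporter Slc2a1 had 857 ± 87.5 CPM in vehicle and 329 ± 104 in transgenic tumours, the endoplasmic oxidase Ero1l 546 ± 137 and 231 ± 66.9, adrenomedullin (Adm) 240 ± 66.0 and 94.7 ± 43.6, and Bnip3 286 ± 35.8 and 140 ± 51.9. Immediate early and heat shock genes rose too, with a median of 0.35 and 13 of 17 higher (camera adjusted p = 1.05e-05; adjusted p = 0.468 with an estimated correlation; 3 members passed adjusted over the list alone and 0 over all genes). Hspa1a and Hspa1b, inducible chaperones, had log2 fold changes of 1.69 ± 0.28 and 1.36 ± 0.28, Fos 1.37 ± 0.35 (1.98 without transgenic replicate 1) and Atf3 0.90 ± 0.27. Mitochondrially encoded genes fell, with a median of -0.49 and 12 of 13 lower (camera adjusted p = 1.19e-06; adjusted p = 0.718 with an estimated correlation; 4 passed adjusted over the list alone and 0 over all genes). Among them mt-Nd1, mt-Nd2, mt-Nd4 and mt-Cytb had -0.70, -0.81, -0.56 and -0.49, and the mitochondrial share of counts was 1.18% and 1.14% in the vehicle and 1.43% and 1.53% in the transgenic libraries. These 4 lists were called again without each of the 6 libraries in turn.

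**Figure D1:**
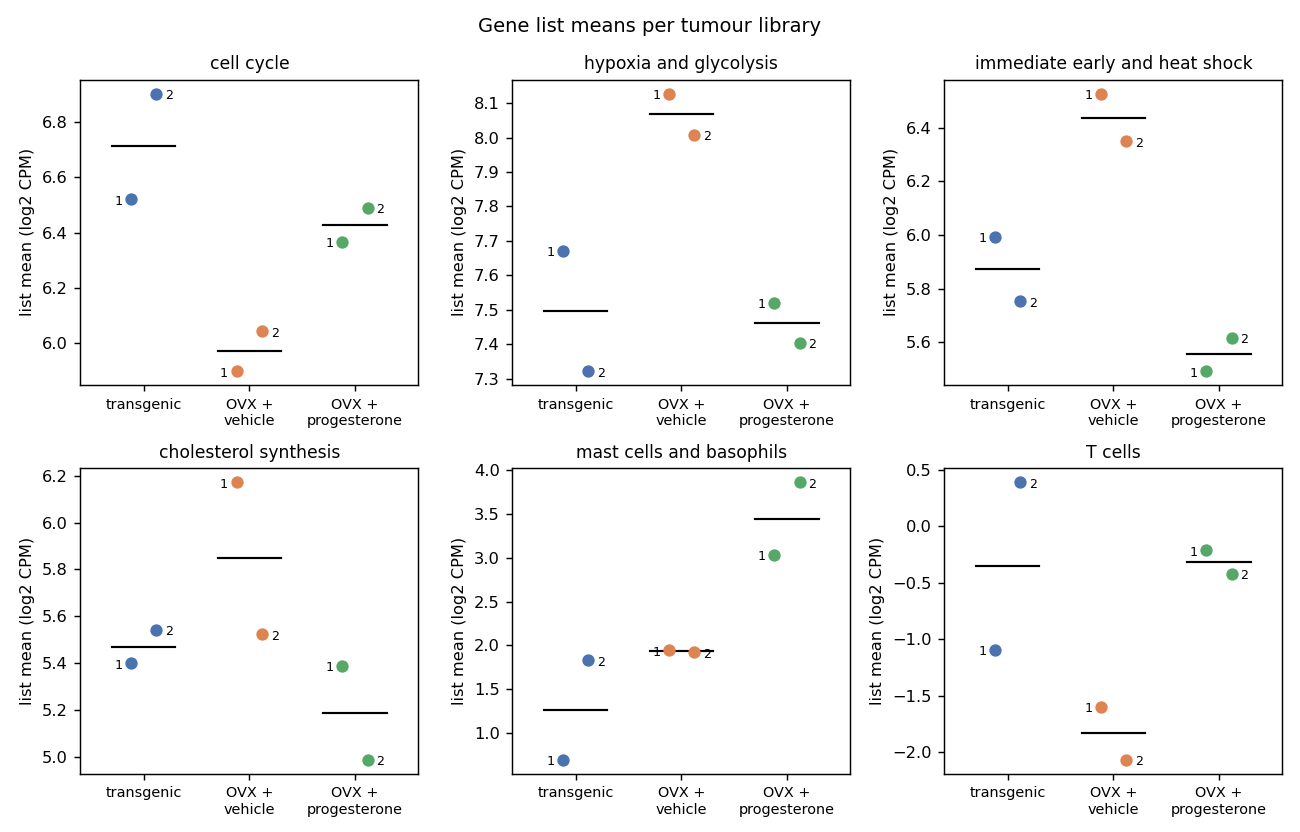
Mean log2 CPM of 6 gene lists in each tumour library, with each point a library labelled by its replicate number and each line the mean of the 2 libraries of a group; OVX stands for ovariectomized. Both vehicle libraries lie below the other 4 in the cell cycle list (5.90 and 6.04) and above them in the hypoxia list (8.13 and 8.01), and both progesterone libraries lie above the other 4 in the mast cell list (3.03 and 3.86).

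Of the immune lists, 6 were called lower in the vehicle than in the transgenic tumours, and none of these calls held without transgenic library 2. The T cell list fell (median -1.38, 9 of 9 lower, camera adjusted p = 0.000274), as did MHC class II presentation (median -2.22, 8 of 8 lower, 0.00793), MHC class I presentation (median -0.59, 14 of 15 lower, 0.00508), interferon response (median -0.28, 20 of 27 lower, 0.0323), cytotoxic and NK cells (median -0.93, 8 of 9 lower, 0.0465) and dendritic cells (median -0.53, 8 of 9 lower, 0.0465). All 6 lost their call with an estimated correlation, at adjusted p = 0.718 for T and dendritic cells and adjusted p = 0.748 for the others. No member passed adjusted over the list alone in any of the 6, nor over all genes. Without transgenic replicate 2 the camera adjusted p was 0.127 for T cells, 0.838 for MHC class II, 0.850 for MHC class I, 0.567 for interferon response, 0.752 for cytotoxic cells and 0.141 for dendritic cells, and both MHC lists changed direction. MHC class I was also not called without vehicle replicate 1 (0.329), interferon response without vehicle replicate 2 (0.112), cytotoxic cells without 4 of the 6 libraries (up to 0.867) and dendritic cells without any 1 of the 6 (up to 0.186). The invariant chain Cd74 had 118 ± 124 CPM in transgenic and 24.2 ± 4.91 in vehicle tumours, the chemokine Cxcl9 19.1 ± 23.4 and 0.429 ± 0.218, and the immunity-related GTPase Iigp1 31.1 ± 26.4 and 2.53 ± 0.176. T cell transcripts were rare, with Cd3d at 0.504 ± 0.241 and 0.0780 ± 0.0353 CPM and Cd8a at 1.92 ± 2.35 and 0.0858 ± 0.121. In the dendritic list, Siglech had 0 counts in both vehicle libraries, and 0.0741 and 0.590 CPM in the transgenic libraries. A fold for it would rest on transgenic library 2 alone and is not given. With Siglech set to 3 counts over the vehicle group, the list median was -0.53.

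Cholesterol synthesis genes rose in the vehicle tumours (median 0.43, 19 of 19 higher, camera adjusted p = 9.33e-06; adjusted p = 0.748 with an estimated correlation), but the call was lost without vehicle replicate 1 (0.675). Hmgcs1, an enzyme of the pathway, had 142 ± 52.0 CPM against 93.7 ± 15.5. Fibroblast markers (median 0.86, 11 of 15 higher, 0.00793), matrix remodelling enzymes (median 0.18, 16 of 24 higher, 0.0110) and mast cell markers (median 0.51, 8 of 9 higher, 0.0338) also rose. With an estimated correlation these had adjusted p = 0.748, adjusted p = 0.513 and adjusted p = 0.748. Fibroblast markers were not called without transgenic replicate 2 (0.223) or vehicle replicate 2 (0.171), matrix enzymes without transgenic replicate 2 (0.0793), vehicle replicate 2 (0.0649) or either progesterone library (0.0620 and 0.0639), and mast cell markers without transgenic replicate 1 (0.482) or either vehicle library (0.0700 and 0.0556). In the matrix list 1 member passed adjusted over the list alone, and 0 did over all genes; in the other 3 lists 0 did by either. That member, the macrophage elastase Mmp12 (ENSMUSG00000049723), lies on chromosome 9 at 7344381 to 7369499 and had 513 ± 77.7 CPM in vehicle and 122 ± 31.5 in transgenic tumours, with a log2 fold change of 2.07 ± 0.29. Mmp10, a stromelysin, had 67.1 ± 43.1 against 16.1 ± 7.76 CPM. Its log2 fold change of 2.05 was 1.18 without vehicle replicate 2 and 2.66 without transgenic replicate 1. Pdgfra, made by fibroblasts, had a log2 fold change of 0.98 ± 0.34 and the mast cell tryptase Tpsb2 0.87 ± 0.41, and decorin (Dcn) had 880 ± 129 against 383 ± 397 CPM.

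By edgeR, no gene passed the test between vehicle and transgenic tumours. The smallest adjusted p was 0.587, and 759 genes had an unadjusted p under 0.05, where 681.6 would be expected by chance. limma-voom called 0 genes, and DESeq2 called 62 (34 higher and 28 lower), among them Scara5, Mmp12 and Rrm2. The gene with the largest rise among those named was the ferritin receptor Scara5 (ENSMUSG00000022032, chromosome 14, 65666403 to 65764826), at 16.8 ± 0.881 CPM in vehicle and 0.933 ± 0.724 in transgenic tumours, a log2 fold change of 4.15 ± 0.56 (5.30 and 3.54 without transgenic replicate 1 and 2). The collagen gene Col23a1 had 3.57 ± 0.50 (2.82 without vehicle replicate 1), the integrin gene Itgb4 1.67 ± 0.31, the Wnt co-receptor Lrp5 0.79 ± 0.14, Vav3 1.21 ± 0.23, Psd3 0.86 ± 0.16 and Fam78b 1.26 ± 0.22. The semaphorin Sema4c had 215 ± 26.9 against 93.5 ± 22.6 CPM. Among the lower genes the interferon-inducible Gbp8 had -2.27 ± 0.48. None of these passed the test by edgeR.

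The second comparison set progesterone tumours against vehicle tumours and asked what progesterone supplementation changed in ovariectomized hosts. Hypoxia and glycolysis genes fell as a list in the progesterone tumours, with a median log2 fold change of -0.56 and 26 of 27 members lower (camera adjusted p = 8.62e-18; adjusted p = 0.342 with an estimated correlation). Cell cycle genes rose, with a median of 0.48 and 24 of 25 higher (camera adjusted p = 7.48e-14; adjusted p = 0.398 with an estimated correlation). Immediate early and heat shock genes fell, with a median of -0.66 and 15 of 17 lower (camera adjusted p = 1.59e-12; adjusted p = 0.158 with an estimated correlation). Cholesterol synthesis genes fell, with a median of -0.72 and 19 of 19 lower (camera adjusted p = 7.48e-14; adjusted p = 0.418 with an estimated correlation). All 4 were called without each library in turn. Members that passed adjusted over the list alone numbered 8 in the hypoxia list, 9 in the immediate early list and 0 in the other 2, with 0 over all genes.

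Egln3, an oxygen-sensing prolyl hydroxylase gene that hypoxia induces (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860), had 224 ± 28.1 CPM in progesterone and 523 ± 82.3 in vehicle tumours, a log2 fold change of -1.23 ± 0.19. Ero1l had -1.27 ± 0.27, Adm -1.30 ± 0.33 and hexokinase 2 (Hk2) -0.85 ± 0.22. The immediate early gene Egr1 had 18.0 ± 0.0320 against 54.5 ± 0.844 CPM, and Atf3, Hspa1a and Hspa1b had log2 fold changes of -1.56 ± 0.28, -1.48 ± 0.28 and -1.42 ± 0.28. Among cell cycle genes, Ccnb1 had 0.61 ± 0.16, Cdc20 0.70 ± 0.20, Plk1 0.65 ± 0.19 and Cenpa 0.68 ± 0.21, and Gtse1, outside the list, 0.88 ± 0.17. In the cholesterol list, Sc5d, Insig1 and Cyp51 had -0.75, -0.75 and -0.72.

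Markers of several host cell types rose in the progesterone tumours. Mast cell and basophil markers had the largest median, 2.54, with 7 of 9 higher (camera adjusted p = 1.43e-05; adjusted p = 0.403 with an estimated correlation). Adjusted over the list alone, 6 members passed as higher and 1 as lower, with 0 over all genes. Tpsb2 had 31.7 ± 10.7 CPM in progesterone and 5.39 ± 0.396 in vehicle tumours, the chymase Cma1 25.4 ± 16.8 and 1.82 ± 0.0974, carboxypeptidase A3 (Cpa3) 30.8 ± 22.8 and 2.28 ± 1.04, and Mcpt4 28.7 ± 15.2 and 1.96 ± 0.447. The log2 fold changes of Cma1, Cpa3 and Mcpt4, 3.80, 3.77 and 3.87, were 2.89, 2.70 and 3.195 without progesterone replicate 2. Without progesterone replicate 1 Cpa3 had 4.37. The lower member was the basophil protease gene Mcpt8, chosen after its values were seen, at 0.164 ± 0.177 and 3.12 ± 1.26 CPM. Macrophage and monocyte markers rose (median 0.61, 13 of 15 higher, camera adjusted p = 6.09e-05; adjusted p = 0.526 with an estimated correlation), with Csf1r at 137 ± 3.40 against 85.4 ± 5.86 CPM and the mannose receptor Mrc1 at 327 ± 151 against 125 ± 22.6. T cell markers rose (median 1.57, 9 of 9 higher, 6.09e-05; adjusted p = 0.460 with an estimated correlation), as did B and plasma cell markers (median 1.88, 5 of 6 higher, 0.00114; adjusted p = 0.342 with an estimated correlation). These 4 lists were called without each library in turn. Their transcripts were rare in the lymphocyte lists, with Cd4 at 1.51 ± 0.266 against 0.0858 ± 0.121 CPM and Jchain, a chain of secreted antibodies, at 2.57 ± 2.27 against 0.0780 ± 0.0353. Adjusted over the list alone 2 B cell members passed and 0 macrophage or T cell members did, and 0 of any passed over all genes.

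Dendritic cell markers rose too (median 0.95, 7 of 9 higher, camera adjusted p = 0.00311; adjusted p = 0.398 with an estimated correlation), but not without progesterone replicate 2 (0.0893). Siglech, at 0 counts in both vehicle libraries, had 1.54 ± 0.159 CPM in progesterone tumours, at least 24.7-fold higher than 3 counts over the vehicle group, and the list median was 0.95 with that bound. MHC class I (median 0.78, 12 of 15 higher, 0.000570), MHC class II (median 1.58, 7 of 8 higher, 0.00662), interferon response (median 0.27, 21 of 27 higher, 0.00584) and the Toll-like receptor pathway (median 0.17, 15 of 19 higher, 0.00528) rose. With an estimated correlation these had adjusted p = 0.576, adjusted p = 0.576, adjusted p = 0.526 and adjusted p = 0.342. None of the 4 was called without progesterone replicate 1 (camera adjusted p of 0.513, 0.470, 0.0715 and 0.156), MHC class I also not without vehicle replicate 1 (0.124) and interferon response not without vehicle replicate 2 (0.0530). Cd74 had 72.4 ± 39.8 CPM in progesterone tumours, H2-Aa 19.9 ± 6.61 against 5.70 ± 0.402 and Tlr2, a sensor of bacterial lipoproteins, 23.6 ± 2.30 against 15.1 ± 0.647. Mitochondrially encoded genes rose (median 0.52, 10 of 13 higher, 6.09e-05; adjusted p = 0.526 with an estimated correlation), but not without progesterone replicate 2 (0.254). Adjusted over the list alone 2 dendritic cell members passed and 0 members of the other 5 lists did, and 0 of any passed over all genes.

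Angiogenesis genes fell in the progesterone tumours (median -0.31, 16 of 22 lower, camera adjusted p = 0.00114; adjusted p = 0.526 with an estimated correlation), as did endothelial markers (median -0.25, 9 of 12 lower, 0.00284; adjusted p = 0.576 with an estimated correlation). Neither was called without progesterone replicate 1 (0.571 and 0.417), where the endothelial list changed direction. The endothelial list means were 3.15 and 4.21 log2 CPM in the progesterone and 4.06 and 4.11 in the vehicle libraries. Von Willebrand factor (Vwf) had 16.2 ± 4.65 CPM against 54.1 ± 3.69, claudin 5 (Cldn5) 7.54 ± 0.280 against 16.0 ± 0.938, angiopoietin 2 (Angpt2) 16.6 ± 5.44 against 45.7 ± 8.49 and placental growth factor (Pgf) 13.5 ± 5.15 against 51.2 ± 11.4, whereas the apelin receptor gene Aplnr had a log2 fold change of 4.79 ± 0.99 (5.52 and 3.24 without progesterone replicate 1 and 2). Tek and Cdh5, also endothelial, had log2 fold changes of 0.81 ± 0.61 and -0.46 ± 0.37. Without progesterone replicate 2 these were -0.53 and -1.17, and without replicate 1 Tek had 1.49. Epithelial to mesenchymal transition genes fell (median -0.20, 15 of 19 lower, camera adjusted p = 0.00359) and were called without each library. With an estimated correlation the camera adjusted p was 0.342. The integrin Itgb3 had 20.2 ± 3.49 against 54.1 ± 4.21 CPM and fibronectin (Fn1) a log2 fold change of -1.05 ± 0.42. The list pools epithelial genes such as Cdh1 and Epcam with mesenchymal genes such as Vim and Fn1, so its fall gives no direction of transition.

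Matrix remodelling enzymes fell by camera (0.0140; adjusted p = 0.379 with an estimated correlation), with a median of -0.19, 13 of 24 lower and a mean of 0.02 of the other sign. That call was lost without progesterone replicate 1 (0.513) or vehicle replicate 2 (0.0657). The members with the smallest p were 4 metalloproteinases of 1 cluster on chromosome 9. Mmp12 had 126 ± 40.0 against 513 ± 77.7 CPM, Mmp10 (7502352 to 7510240) 6.14 ± 2.30 against 67.1 ± 43.1, the stromelysin Mmp3 (7445822 to 7455975) 283 ± 122 against 2226 ± 193, and the collagenase Mmp13 (7272514 to 7283331) 14.6 ± 1.64 against 64.2 ± 48.8. The unfolded protein response fell (median -0.19, 14 of 19 lower, 0.00559; adjusted p = 0.505 with an estimated correlation), but not without progesterone replicate 2 (0.380) or vehicle replicate 2 (0.0648), with Atf4 at 224 ± 21.6 against 309 ± 63.7 CPM. Red blood cell genes fell (median -3.48, 8 of 8 lower, 0.00114; adjusted p = 0.539 with an estimated correlation), but not without vehicle replicate 1 (0.202) or progesterone replicate 1 (0.0601). The haemoglobin gene Hbb-bt was at 317 and 36.3 CPM in the vehicle libraries and at 8.38 and 17.0 in the progesterone libraries. Adjusted over the list alone, 3 angiogenesis members passed as lower and 1, Aplnr, as higher. In the other lists 2 endothelial, 3 matrix, 1 transition and 1 unfolded protein response members passed as lower and 0 red blood cell members passed, with 0 over all genes.

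By edgeR, no gene passed the test between progesterone and vehicle tumours. The smallest adjusted p was 0.668, and 721 genes had an unadjusted p under 0.05, where 681.6 would be expected by chance. limma-voom called 0 genes, and DESeq2 called 73 (33 higher and 40 lower). Haem oxygenase 1 (Hmox1, ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), which degrades haem, had 389 ± 23.6 CPM in progesterone and 184 ± 5.69 in vehicle tumours (log2 fold change 1.08 ± 0.17, adjusted p = 0.705). Other higher genes were the axon guidance genes Plxna4 (1.18 ± 0.23) and Draxin (2.74 ± 0.55, and 3.40 without vehicle replicate 2), the phosphatase Ptpn13 (1.41 ± 0.29) and the matrix gene Tnxb (2.99 ± 0.64, and 3.66 and 1.71 without progesterone replicate 1 and 2). The lower genes were led by Trp53i11 (ENSMUSG00000068735, chromosome 2, 93187548 to 93201759), at 56.0 ± 7.49 against 146 ± 6.17 CPM (-1.38 ± 0.16), and included Fam167a (-1.69 ± 0.26) and the growth factor Hbegf (-0.86 ± 0.15).

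**Figure D2:**
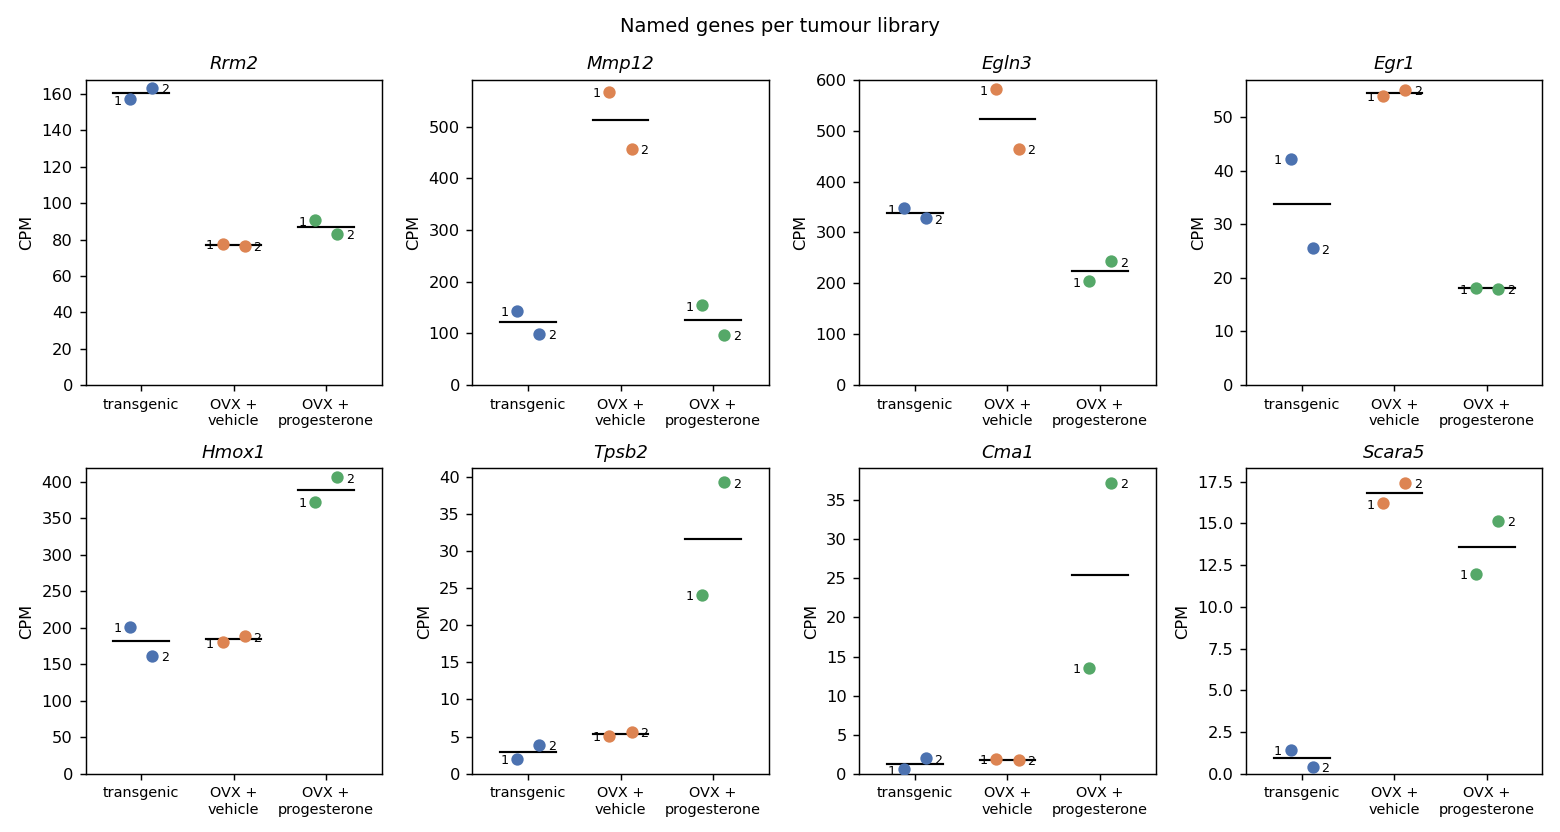
TMM-scaled CPM of 8 named genes in each tumour library on linear axes from 0, with each point a library labelled by its replicate number and each line the mean of the 2 libraries of a group; OVX stands for ovariectomized. Mmp12 is at 568 and 458 CPM in the vehicle libraries and at most 154 in the other 4, and Scara5 is at 1.44 and 0.421 CPM in the transgenic and 16.2 and 17.4 in the vehicle libraries; no gene passed the test over all genes.

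The third comparison set progesterone tumours against transgenic tumours, the groups that differ by both ovariectomy and supplementation. Mast cell and basophil markers rose in the progesterone tumours, with a median log2 fold change of 3.42 and 7 of 9 higher (camera adjusted p = 5.98e-07; adjusted p = 0.919 with an estimated correlation), and this was the only 1 of the 9 called lists that was called again without each of the 6 libraries. Adjusted over the list alone, 6 members passed as higher and 1 as lower, and 0 passed over all genes. Tpsb2 (ENSMUSG00000033825, chromosome 17, 25366305 to 25369098) had 31.7 ± 10.7 CPM against 2.96 ± 1.36, a log2 fold change of 3.42 ± 0.43 (adjusted p = 0.798). Cma1 had 4.31 ± 0.72 (3.67 and 5.40 without transgenic replicate 1 and 2, and 3.40 without progesterone replicate 2), Tpsab1 2.99 ± 0.53 (2.36 and 4.08 without transgenic replicate 1 and 2) and Ms4a2, a chain of the IgE receptor, 3.53 ± 0.70. The lower member was Mcpt8, chosen after its values were seen, at 0.164 ± 0.177 CPM against 0.593 and 3.41 in the transgenic libraries.

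Cell cycle genes fell (median -0.32, 23 of 25 lower, camera adjusted p = 3.98e-06; adjusted p = 0.919 with an estimated correlation), but not without transgenic replicate 2 (0.186), and Rrm2 had 86.9 ± 5.17 against 160 ± 4.51 CPM. Endothelial markers fell (median -0.48, 11 of 12 lower, 1.88e-05; adjusted p = 0.919 with an estimated correlation), but not without progesterone replicate 1 (0.634), with Cldn5 at -1.14 ± 0.25. Angiogenesis genes fell (median -0.28, 15 of 22 lower, 0.00940; adjusted p = 0.919 with an estimated correlation), but not without progesterone replicate 1 (0.909) or transgenic replicate 1 (0.442), with the Notch ligand Dll4 at -1.14 ± 0.37 (-1.79 without progesterone replicate 2). Immediate early and heat shock genes fell (median -0.22, 12 of 17 lower, 0.00940; adjusted p = 0.919 with an estimated correlation), but not without transgenic replicate 1 (0.347), with Ier2 at -0.71 ± 0.20 and Egr1 at -0.91 ± 0.26. Cholesterol synthesis genes fell (median -0.26, 17 of 19 lower, 0.00219; adjusted p = 0.979 with an estimated correlation), but not without progesterone replicate 2 (0.631) or transgenic replicate 2 (0.0580). Macrophage markers rose (median 0.37, 13 of 15 higher, 7.55e-05; adjusted p = 0.919 with an estimated correlation), but not without transgenic replicate 1 (0.766), with Csf1r at 0.76 ± 0.25. Fibroblast markers rose (median 0.82, 13 of 15 higher, 0.00181; adjusted p = 0.919 with an estimated correlation), but not without progesterone replicate 2 (0.892) or transgenic replicate 2 (0.403), with Pi16 at 48.8 ± 64.2 against 2.17 ± 1.34 CPM and Col1a2 at 557 ± 742 against 58.6 ± 68.0. Red blood cell genes fell (median -3.46, 8 of 8 lower, 0.0366; adjusted p = 0.979 with an estimated correlation), but not without transgenic replicate 1 (0.657, with the direction changed) or either progesterone library (0.233 and 0.137). Adjusted over the list alone 1 cell cycle and 1 endothelial member passed, and 0 of any of these lists passed over all genes.

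By edgeR, no gene passed the test between progesterone and transgenic tumours. The smallest adjusted p was 0.798, and 718 genes had an unadjusted p under 0.05, where 681.6 would be expected by chance. limma-voom called 0 genes, and DESeq2 called 47 (32 higher and 15 lower). Scara5 had 13.6 ± 2.24 CPM against 0.933 ± 0.724 and Hmox1 389 ± 23.6 against 182 ± 28.3. Txnip, which binds thioredoxin, had a log2 fold change of 1.07 ± 0.21, the tetraspanin Cd37 1.41 ± 0.29 and Serpinb1a 2.96 ± 0.62 (2.10 without progesterone replicate 2). Lower genes were Trp53i11 (-1.16 ± 0.16), Hbegf (-0.99 ± 0.15), the apoptosis gene Pmaip1 (-3.01 ± 0.56, and -3.60 and -1.997 without transgenic replicate 1 and 2), Igfbp3 (-1.49 ± 0.31), Itgb3 (-0.87 ± 0.20) and the ribosomal protein genes Rpl29 (-0.85 ± 0.20) and Rpl17 (-0.80 ± 0.19). Klf9 had 36.2 ± 5.20 against 72.3 ± 1.16 CPM.

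The comparisons of vehicle with transgenic and of progesterone with vehicle tumours share the vehicle libraries, so chance moves them in opposite directions. Across genes the Pearson correlation of their log2 fold changes was -0.52, against -0.51 in 20 simulations without any effect, and the covariance was -0.188 against -0.139 simulated. By edgeR 0 genes were called in opposite directions, at most 1 in a simulation. DESeq2 called 11, where the simulations gave 4.15 on average and at most 10, and independent lists would give 0.182. They were Mmp10, Mmp12, Mmp1b, Col23a1, Hspa1a, Hspa1b, Fam78b, Ero1l, Adm, Dnajc9 and mt-Nd4, of which the last 2 were lower in vehicle tumours and the others higher. DESeq2 called 62 and 73 genes in these comparisons, but 19.4 per comparison on average in the simulations. More calls leave more room for shared ones, so the simulated numbers do not decide whether 11 is an excess. Of the 12 lists called by camera in both comparisons, 11 had opposite directions, and mast cell markers rose in both. The simulations drew genes independently, so they give no expected number of such lists. For vehicle and progesterone tumours, each against the same transgenic libraries, the correlation was 0.33 against 0.50 simulated and the covariance 0.106 against 0.136. DESeq2 called 6 genes in the same direction in both, against 3.75 simulated on average, at most 8, and 0.118 for independent lists. These were Scara5, Itgb4, Sema4c, Rrm2, Plet1 and Col24a1. The same limit holds here, with 62 and 47 genes called by DESeq2.

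The hormone receptor genes given here did not pass the test in any comparison. The progesterone receptor gene Pgr had 5 counts in all 6 libraries together and the luteinizing hormone receptor gene Lhcgr 3, and neither passed the filter, so differences in them were not detectable at this depth. The glucocorticoid receptor gene Nr3c1 was at 143 ± 20.5 CPM in transgenic, 158 ± 16.8 in vehicle and 129 ± 14.7 in progesterone tumours. Genes of membrane-associated progesterone-binding proteins were expressed, Pgrmc1 at 102 ± 17.1 CPM in vehicle and 75.1 ± 9.96 in progesterone tumours and Pgrmc2 at 94.6 ± 4.41 and 87.8 ± 0.583. In transgenic, vehicle and progesterone tumours the membrane receptor gene Paqr7 was at 26.0 ± 1.61, 29.5 ± 6.70 and 27.1 ± 10.1 CPM and Paqr8 at 7.62 ± 1.59, 6.45 ± 2.19 and 8.25 ± 0.795. Oestrogen receptor genes Esr1 and Esr2 were at 14.6 ± 12.7 and 1.21 ± 0.0130 CPM in vehicle and 9.99 ± 4.78 and 2.09 ± 0.327 in progesterone tumours. The mineralocorticoid receptor gene Nr3c2 and Gper1 averaged 0.759 CPM or less in each group.

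In all, 16 lists were called by camera in none of the 3 comparisons. In the order vehicle minus transgenic, progesterone minus vehicle and progesterone minus transgenic, the median log2 fold changes were 0.29, -0.26 and 0.08 for progesterone and glucocorticoid receptor targets, 0.26, -0.25 and 0.0095 for oestrogen receptor targets, and 0.17, -0.11 and -0.04 for hormone receptors. They were 0.17, 0.13 and 0.52 for steroid synthesis and metabolism, -0.04, 0.11 and 0.04 for oxidative phosphorylation, and 0.09, -0.02 and 0.03 for ribosomal proteins. They were -0.08, -0.34 and -0.55 for inflammatory cytokines and chemokines, -0.04, 0.13 and -0.08 for immune suppression and checkpoints, and 0.0017, 0.0090 and 0.11 for drug efflux and resistance. Among cell type markers they were 0.26, -0.12 and -0.15 for neutrophils, -0.34, 0.63 and 0.43 for pericytes and smooth muscle, -0.28, 0.46 and 0.18 for adipocytes, and -0.40, -0.51 and -0.71 for skeletal muscle. They were 0.31, -0.07 and 0.13 for mammary epithelium, -0.12, -0.03 and 0.03 for nerve and Schwann cells, and -0.08, 0.26 and 0.04 for the lung epithelial lineage. Among these lists the drug efflux list had 1 member that passed adjusted over the list alone in each comparison and the pericyte list 1 in progesterone minus transgenic, with 0 over all genes. Over the 114 pairs of list and comparison, the median, the mean and the test differed in sign in 18, of which 1 was called.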

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

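The edgeR fits with its newer dispersion method and with robust estimation were chosen after seeing the data; they called 0 genes in each comparison, as did all other edgeR and limma-voom settings except the unfiltered fit. Without a filter on low counts edgeR called 12 genes in vehicle minus transgenic, 92 in progesterone minus vehicle, 28 in progesterone minus transgenic and 6 in opposite directions. DESeq2 called 62, 73, 47 and 11. In simulations without any effect DESeq2 still called 19.4 genes per comparison on average and edgeR 0.8; for the calls of the unfiltered fit the cause was not tested. Leaving out each library gave 0 genes in each comparison and 0 in opposite directions, with a group of 1 library assumed to vary like the others. The lists called by camera, 14, 20 and 9, became 0, 0 and 0 with an estimated correlation and 0, 1 and 0 with fry (immediate early and heat shock genes). In vehicle minus transgenic the estimated correlation was 0.44 for cell cycle, 0.16 for hypoxia, 0.74 for cholesterol synthesis and 0.93 for MHC class II genes. These exceed the preset 0.01, and at such correlations the preset test gives p-values that are too small. A higher correlation does not explain every loss, since lists with estimates below the preset lost their calls too. In progesterone minus vehicle these included immediate early (-0.02), B and plasma cell (-0.05), transition (-0.03) and Toll-like receptor genes (-0.004). For the immediate early list there, the unadjusted camera p went from 1.68e-13 to 0.00415. The 2 forms of the test thus differ in more than the correlation, and the cause of these losses was not tested. With median-of-ratios factors all these calls remained. Leaving out each library gave 9 to 20, 16 to 22 and 9 to 16 lists. Same-numbered libraries deviated together at r = -0.13 (progesterone and vehicle), -0.17 (progesterone and transgenic) and 0.08 (vehicle and transgenic) across genes. With 2 libraries per group each r rests on 1 difference per group, so pairing by number is neither shown nor excluded. The replicate block gave 0 genes in each comparison and 16, 20 and 9 lists, with all main calls kept. The 3 counts that a count of 0 allows limit what can be seen of rare transcripts such as Pgr.

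Of 3923 values of the named genes under alternatives, 3743 kept direction and side of the threshold, 141 kept direction and passed it, and 39 changed direction; beyond the fewer libraries the cause was not tested. Of the 236 pairs of named gene and comparison, 87 moved by over 1.5 times without 1 library. With limma-voom Nr3c2 had -0.011 in progesterone minus vehicle and -0.24 in progesterone minus transgenic, and Esr1 0.22 in the latter. The other changes came from leaving out 1 library, where the log2 fold change in vehicle minus transgenic ranged from -0.15 to 0.10 for Pgrmc2, -0.021 to 0.52 for Pgrmc1, -0.635 to 0.075 for Paqr8, -0.068 to 0.40 for Paqr7, -1.12 to 0.39 for Nr3c2, -0.95 to 2.21 for Esr1, -3.10 to 0.34 for H2-Q7, -1.71 to 0.035 for Tap1, -2.99 to 0.14 for H2-Ab1 and -0.12 to 1.61 for Cma1. In progesterone minus vehicle it ranged from -0.56 to 0.22 for Paqr7, -1.12 to 1.17 for Nr3c2, -1.25 to 0.81 for Esr1, -0.53 to 1.49 for Tek and -1.17 to 0.012 for Cdh5. In progesterone minus transgenic it ranged from -0.46 to 0.080 for Pgrmc1, -0.085 to 0.34 for Paqr8, -0.38 to 0.40 for Paqr7, -1.26 to 0.74 for Nr3c2, -0.28 to 0.012 for Nr3c1, -1.95 to 0.053 for Gper1, -0.13 to 0.32 for Esr2, -0.91 to 1.65 for Esr1, -0.70 to 6.38 for Mfap5, -0.86 to 5.72 for Col1a2, -4.85 to 0.85 for Hbb-bt, -4.49 to 1.01 for Hba-a1 and -4.30 to 0.62 for Alas2. Over the same omissions the camera adjusted p ranged from 3.74e-07 to 0.850 for MHC class I and 8.70e-10 to 0.838 for MHC class II in vehicle minus transgenic, 5.22e-09 to 0.417 for endothelial cells in progesterone minus vehicle and 1.23e-08 to 0.657 for red blood cells in progesterone minus transgenic.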

Other observations

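All genes in this paragraph and the next were chosen after their values were seen, and none passed the edgeR test over all genes. Cathepsin K (Ctsk) was at 174 and 126 CPM in the progesterone libraries, 7.03 and 88.6 in the vehicle libraries and 10.3 and 15.9 in the transgenic libraries. The acid phosphatase Acp5 was at 133, 57.0, 4.84, 93.2, 9.37 and 12.4 CPM in the same order, and Atp6v0d2, a proton pump subunit, at 16.1, 12.3, 0.789, 9.54, 1.18 and 2.99. In progesterone minus transgenic, Ctsk had a log2 fold change of 3.52 (edgeR adjusted p = 0.914, higher in 2 of 2 libraries). The related metalloproteinase genes Mmp1a and Mmp1b were at 23.6 and 23.8 CPM in vehicle library 1, 3.60 and 6.15 in vehicle library 2 and at most 4.56 in the other 4.

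Single libraries stood apart in the values of some genes. Transgenic library 2 had Cxcl9 at 35.7 CPM, where the other 5 had 0.274 to 8.46, Lama1 at 12.2 (0.0773 to 0.901), Greb1, an oestrogen-responsive gene, at 67.5 (2.51 to 18.7) and Col3a1 at 1414 (3636 to 8604). Its list means were 5.51 log2 CPM for MHC class II, where the other 5 had at most 4.66, and 1.77 for neutrophils (2.54 to 3.81). They lay outside the other 5 in further lists as well. Among these were cell cycle (6.90 against at most 6.52), hypoxia (7.32 against at least 7.40) and fibroblasts (5.57 against at least 6.15). Progesterone library 2 had Pi16 at 94.2 CPM (1.22 to 3.71 in the others), Mfap5 at 37.1 (0 to 2.57) and Cd55 at 21.5 (0.463 to 1.27). Vehicle library 1 and transgenic library 1 had Alas2 at 85.3 and 81.6 CPM against 2.70 to 9.11 in the other 4, and the placental prolactin-family gene Prl2c3 at 38.9 and 80.0 against 1.85 to 15.9.

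The tests below on library depth, host cells, freezing delay, skin, fat and connective tissue were chosen after the values were seen; the splits of the libraries were fixed beforehand. With 4 libraries per comparison there are 3 splits into 2 and 2, too few for a share under 0.05. In vehicle minus transgenic the real split called 14 lists and the highest other split 13, with 1 of 3 splits at least as high as the real one. In progesterone minus vehicle these were 20 and 10, with 1 of 3. In progesterone minus transgenic they were 9 and 15, with 3 of 3.

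The vehicle libraries lay apart from the other 4 in the cell cycle and hypoxia lists, and in the cell cycle list both progesterone libraries (6.37 and 6.49) also lay below both transgenic ones (6.52 and 6.90). Library depth does not account for it, since the deepest and the shallowest library were both vehicle and differed by 0.144 log2 CPM in the cell cycle list, less than the gap of 0.323 to the nearest other library. A larger share of host cells stays open. Of 7 host lists chosen for this test 3 were above 5 CPM, and 1 of these was higher in the vehicle libraries (macrophages -0.31 ± 0.28, fibroblasts -0.09 ± 0.61, endothelial cells 0.11 ± 0.28 log2 CPM, SE). The T, B, dendritic and mast cell lists, under 5 CPM in the vehicle libraries, were at -1.50 ± 0.39, -1.63 ± 0.31, -0.88 ± 0.21 and -0.42 ± 0.69. Over the 7 chosen lists, as first tested, 3 were lower by over 2 SE and argued against a larger share of those cells. The limit of 5 CPM was set after these values were seen. Host lists outside the 7 went both ways. In vehicle, progesterone and transgenic tumours the list means were 3.28, 2.78 and 2.79 log2 CPM for neutrophils and 3.53, 3.80 and 3.74 for pericytes. Red blood cells were at 4.49, 1.86 and 3.83, with 6.16 and 2.82 in the 2 vehicle libraries. Delay before freezing is not in the labels and cannot be told apart from ovariectomy without progesterone, because the immediate early list was already called higher in vehicle tumours and its gap of 0.355 log2 CPM to the highest other library decides nothing, and the hormone state of the host stays open as an untested biological explanation.

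Mast cell genes other than Mcpt8 were mostly higher in both progesterone libraries, and the list summed to 143 and 231 CPM against 61.0 and 63.2 in the vehicle libraries. Attached skin with epidermis is argued against, because Krt1, Krt5, Krt10 and Krt14 together differed by 0.386 CPM and reached 1.58 CPM at most. The fat genes Adipoq, Plin1, Cidec and Lep together differed by 0.464 CPM. In progesterone library 1 they were at 0.0773 CPM, between the vehicle libraries (0.171 and 0.0530), which argues against attached fat there. In progesterone library 2 they were at 1.07 CPM, where the others had at most 0.171, so some fat in that library stays open. More connective tissue, where mast cells reside, is neither supported nor excluded: the mean of the fibroblast list differed by 0.71 log2 CPM, but the progesterone libraries were at 6.15 and 8.12 and the vehicle libraries at 6.17 and 6.68, so library 2 carried it. The fibroblast list was not called (camera adjusted p = 0.851), with a median log2 fold change of -0.02 and 7 of 15 members higher. Connective tissue content and progesterone treatment cannot be told apart with 2 libraries, and the treatment stays open as an untested biological explanation.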
